A study of Mus musculus with 4 samples.

How the data were processed

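RNA from the testes of 4 C57BL/6 mice at postnatal day 56 was sequenced from TruSeq libraries, with 2 libraries labelled WT and 2 labelled Ppp2ca-cKO (genotype Ppp2ca-/-). The labels do not state that samples with the same replicate number share a litter or a day, nor whether the libraries were stranded, so antisense and overlapping genes cannot be told apart. They describe one testis per sample without saying how animals were assigned, so p-values measure the spread between these samples.

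Per the file headers, the authors' table holds expected counts and FPKM values per Ensembl transcript and library, together with their differential expression statistics and an annotation. The deposited expected counts are estimates that need not be whole, and the deposited FPKM values divide them by transcript length and library total. The authors' mean normalized count per transcript is a signal over the 4 libraries, and the deposited log2 fold changes and p-values are theirs. The deposited files of single samples repeat the FPKM values of that table for the same 11304 transcripts. The submitters' processing notes name the genome build mm9. The gene coordinates in the table were nevertheless identical to those of GRCm38 for 98.5% of the transcripts whose gene is in GENCODE vM21, which holds the genes of 98.7% of them, so coordinates are given as GRCm38 and are those of the gene. The aligner and the counting tool are not given in the sources used here. Gene ontology terms were taken from the table's annotation.

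Every listed transcript has an adjusted p of at most 0.05 and an absolute log2 fold change of at least 1 in the authors' deposited table, so the table is a selection and transcripts that did not change are not analysed here. The selection also means that the spread was estimated on transcripts already called, which lowers it. From the ratio of the deposited p-values to adjusted p-values, the authors tested 64840 transcripts, of which 13739 had an adjusted p under 0.05, and 2435 of these were left out of the list by the fold threshold. Their size factors were recovered from the mean normalized counts with a largest relative misfit of 4.9e-10, as 0.818 and 0.854 for the WT and 1.24 and 1.25 for the cKO. Library totals were recovered from reads, length and FPKM of transcripts of at least 2000 bases and 500 reads, with a median misfit of 0.00735% to 0.0144%. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

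Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, genotype only) in R 4.3.3 after filterByExpr with a minimum count of 10, which kept 10716 transcripts. The planned TMM scaling assumes that most transcripts do not change. Since the table holds only transcripts the authors called, the authors' size factors were used in its place, a choice made after seeing the data, and TMM is given as an alternative. The Benjamini-Hochberg adjustment ran over all 64840 transcripts, with those outside the table given the largest possible p-value, and the threshold was an adjusted p under 0.05. The common biological coefficient of variation was 32.5%, with 2 residual and 3.51 prior degrees of freedom. A fold against a genotype at 0 was bounded with 3 counts over the group. Normalized counts are counts divided by the size factors, and errors of log2 fold changes are standard errors of the fit. The 2 libraries of a genotype were compared over 10349 transcripts and were not duplicates, with a chi-square per degree of freedom of 33.1 in the WT and 27.7 in the cKO and a standard deviation of their log2 difference of 0.76 and 1.03.

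The lead transcript of a gene is its listed transcript with the highest mean normalized count, which gave 7453 genes, of which 7119 were tested. Before the data were examined, 24 gene lists were fixed, together with the rule for named genes: Ppp2ca and Ppp2cb, the first 2 tested genes of each list, the 5 largest changes each way among calls with a mean of at least 10 CPM that no replicate contradicts, predicted genes skipped, and the called member with the smallest p of the rarer direction in lists called both ways. Some genes that this rule takes, and 1 list, are not reported here. Other members of the lists named as examples were chosen after their values were seen. The 20 lists with at least 3 tested lead transcripts were tested against the other listed lead transcripts with camera in limma 3.58.1 (preset correlation 0.01, two-sided), with an estimated correlation and fry as alternatives. X-linked and autosomal genes were compared by the difference of medians, camera and Fisher's exact test in scipy 1.17.1. Crabp1 is in both the differentiating spermatogonia and the retinoic acid list, and Ybx2 in both the spermatocyte and the round spermatid list.

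The alternatives were RLE, upper quartile, library total and equal Sertoli count scaling, no filter or 1 CPM in 2 samples, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 2, a replicate block, and leaving out each library. The fit was tested on simulated counts for the 10716 transcripts, with 50 changed at each fold, far fewer than were called in the data, which makes the adjustment stricter. With the adjustment over all transcripts it called 4% of transcripts changed 2-fold, 50% of those changed 4-fold, 82% of those changed 8-fold and 98% of those changed 16-fold, and it called 0 of 10486 unchanged transcripts, of which 4.64% had an unadjusted p under 0.05. Simulated dispersions followed the fitted trend, without scatter of single transcripts around it, so these shares need not hold for the data.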

Results

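Testis RNA was sequenced from wild-type (WT) mice and from mice labelled Ppp2ca-cKO at postnatal day 56, with 2 libraries per genotype. Ppp2ca encodes a catalytic subunit of protein phosphatase 2A (PP2A), a serine/threonine phosphatase. The series asks how this subunit bears on the entry of male germ cells into meiosis. The values cover 11304 Ensembl transcripts of 7453 genes, all of which the authors had called different between the genotypes. Library totals recovered from the FPKM values were 17611817 and 19779735 reads in the WT and 18681891 and 19837227 in the cKO. The listed transcripts took 43.3% and 44.5% of the reads in the WT libraries and 24.4% and 25.5% in the cKO libraries. A gene is described below by its most abundant listed transcript, with normalized counts as mean ± SD (n = 2) and, for single transcripts and genes, adjusted p-values from edgeR's quasi-likelihood test over all 64840 transcripts the authors tested. The counts of members adjusted over the list alone rest on transcripts the authors picked on these same samples, so they are not independent evidence. None of the listed transcripts belonged to Ppp2ca or to its paralog Ppp2cb (0 of 11304 each), so the targeted gene was not analysed here and the genotype labels were taken as given.

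In the comparison of the genotypes, transcripts of haploid germ cells fell in the cKO. In the elongating spermatid list, 32 of 33 tested members fell, with a median log2 fold change of -3.96. In the round spermatid list, 28 of 32 tested members fell, with a median of -3.08. Transcripts of Sertoli cells, the somatic cells that support germ cells, moved the other way, with 11 of 22 tested members higher and a median of 1.35. Transcripts of the steroid-producing Leydig cells and of leukocytes were also higher, in 9 of 13 and 5 of 10 tested members, with medians of 1.56 and 1.89. These counts moved with the scaling. Under TMM of the listed transcripts, which moves the cKO over WT ratios up, 21 elongating and 15 round spermatid members fell, with medians of -2.48 and -1.60, and 21 Sertoli, 13 Leydig and 10 leukocyte members rose. With equal Sertoli counts, which moves the ratios down and sets the Sertoli list to about 0 by construction, 0 Sertoli, 1 Leydig and 0 leukocyte members passed, with 0, 1 and 1 at an unadjusted p under 0.05.

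**Figure D1:**
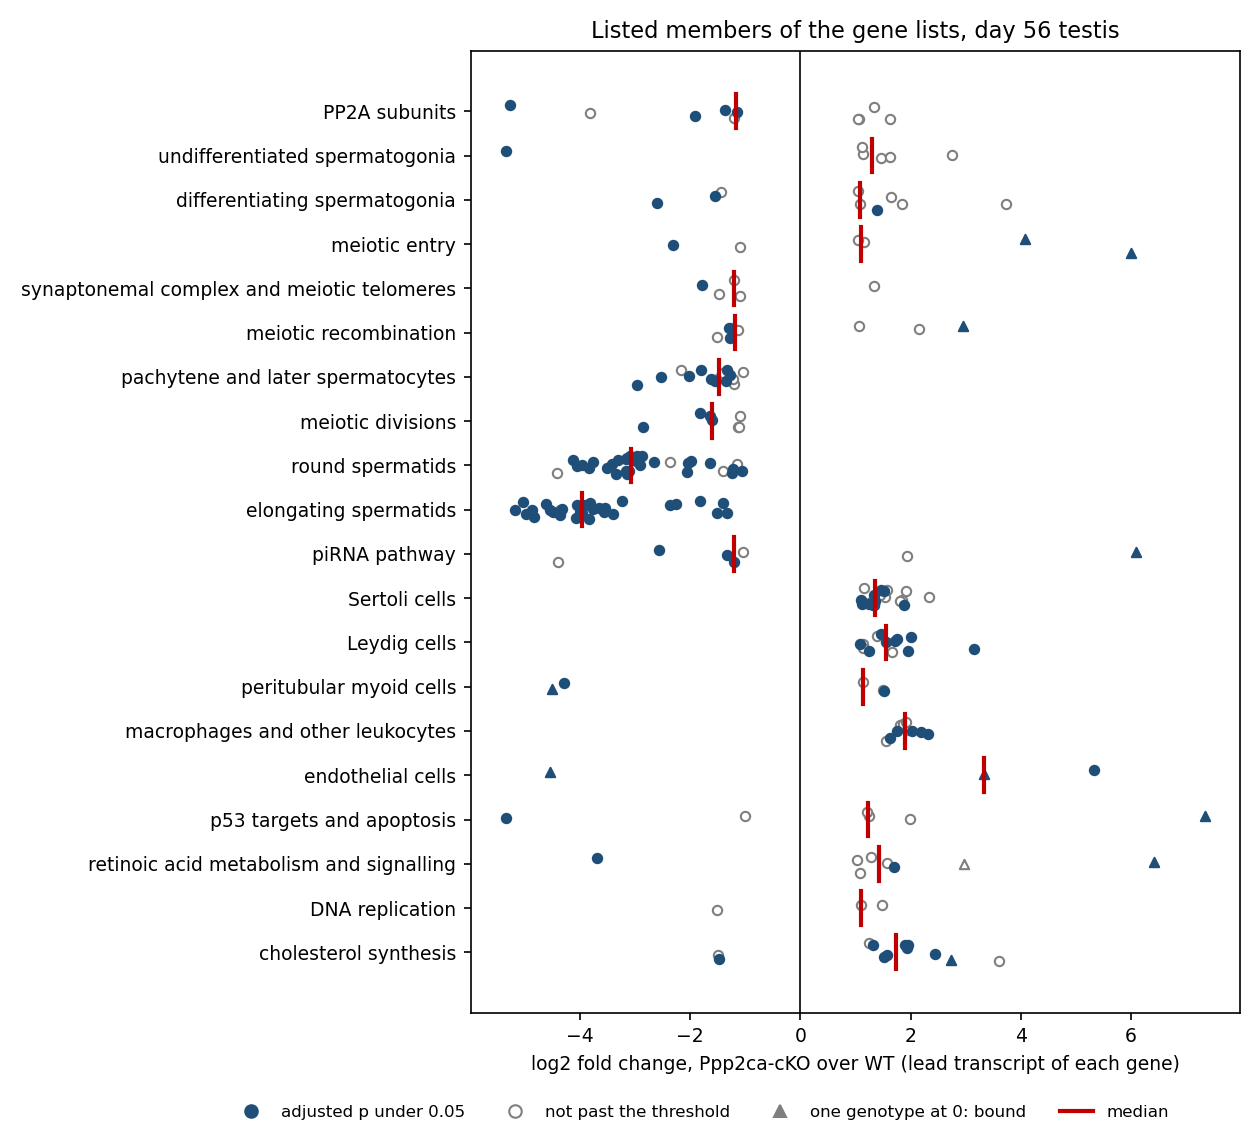
Each point is the lead transcript of a listed gene, placed by its log2 fold change (cKO over WT, 2 libraries each), with filled points past an adjusted p of 0.05, triangles at the bound that a genotype at 0 allows and red bars at list medians. The elongating and round spermatid medians lie at -3.96 and -3.08 and the Sertoli, Leydig and leukocyte medians at 1.35, 1.56 and 1.89, while the medians of PP2A, synaptonemal complex, recombination and piRNA lists turn positive under TMM and RLE scaling of the listed transcripts, the spermatocyte median does so under RLE, the differentiating spermatogonia, meiotic entry, myoid, p53 and DNA replication medians turn negative with equal Sertoli counts, and the endothelial median turns negative without a low-count filter.

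Among elongating spermatid transcripts, Tnp1, a transition protein that replaces histones before the protamines, fell from 18110 ± 5340 to 633.7 ± 516 (log2 fold change -4.84 ± 0.72 SE, adjusted p = 0.0246). The protamine Prm2 fell from 58100 ± 3440 to 1591 ± 1670 (-5.19 ± 0.96, adjusted p = 0.036). The fibrous sheath component Akap4 (log2 fold change -3.84) and the mitochondrial capsule protein Smcp (-4.37) fell too. The protamine Prm1 (chromosome 16, 10796326 to 10805839, GRCm38) stood at 46590 ± 15600 in the WT and at 364 and 4149 in the 2 cKO libraries. Its log2 fold change of -4.37 ± 1.15 did not pass the test (adjusted p = 0.0852). All 33 members fell when adjusted over the list alone. The elongating spermatid transcripts were also higher in cKO replicate 2 than in cKO replicate 1, with a median log2 ratio of 1.37, against 0.57 for the round spermatid list and -0.12 for the Sertoli list. Without cKO replicate 2, the number of elongating spermatid members that fell was 33, and without cKO replicate 1 it was also 33, with list medians of -4.75 and -3.45 (-3.41 and -2.82 for the round spermatid list).

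In the round spermatid list, the acrosomal vesicle gene Acrv1 (chromosome 9, 36693220 to 36698843, GRCm38) fell from 2900 ± 397 to 345.0 ± 1.08 (-3.07 ± 0.25, adjusted p = 0.0154). Crem, a transcription factor required for spermatid gene expression, fell from 1056 ± 20.6 to 252.7 ± 103 (-2.06 ± 0.36, adjusted p = 0.0327). Spaca7 (-4.13) and the testis-specific kinase Tssk2 (-3.84) fell too. All 32 members fell adjusted over the list alone. Against the other listed genes, both spermatid lists were lower by camera with a preset correlation of 0.01, with adjusted p = 4.28e-06 for elongating and 7.29e-06 for round spermatids. Both calls were lost with adjusted p = 0.574 with an estimated correlation.

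**Figure D2:**
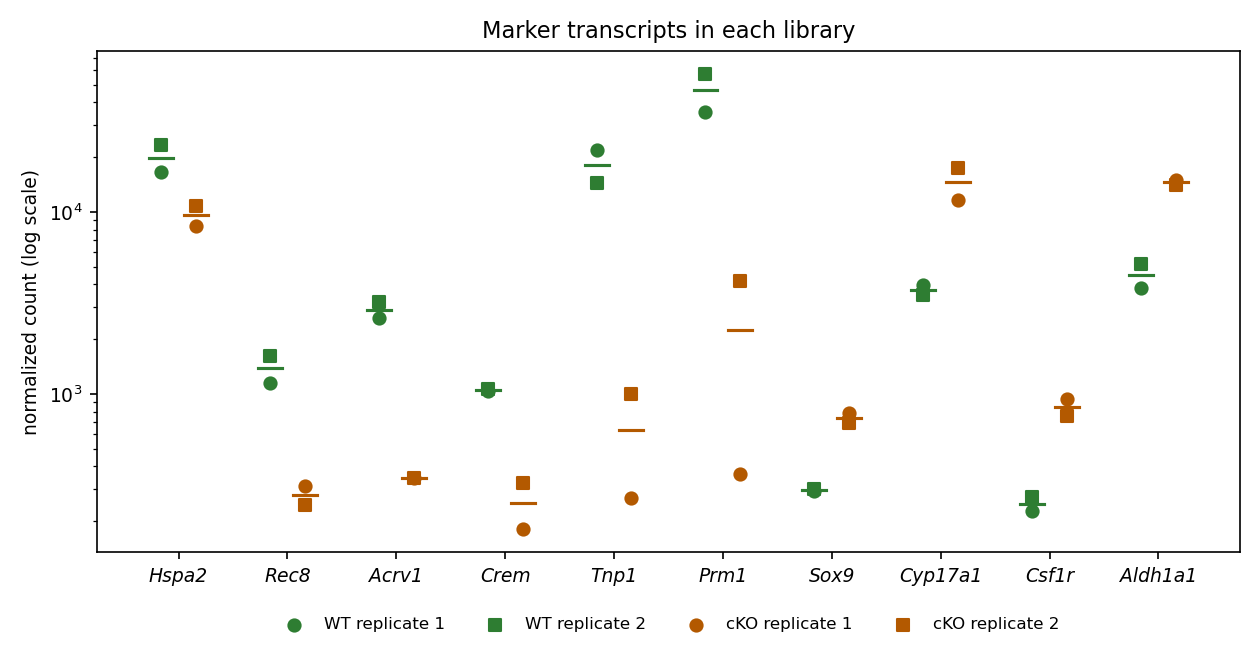
Normalized counts (log axis) of 10 transcripts in each of the 4 libraries, with WT in green, cKO in orange, circles for replicate 1, squares for replicate 2 and short bars at genotype means (n = 2). Prm1 stood at 364 and 4149 in the cKO libraries against 35590 and 57580 in the WT, Acrv1 at 346 and 344 against 2619 and 3181, and Sox9 at 781 and 694 against 294 and 299.8; Hspa2 turned higher in the cKO under TMM, RLE and upper quartile scaling.

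Listed transcripts of meiotic stages were lower by less. Of 23 spermatocyte and 24 division members, 8 and 17 were not among the listed transcripts and so were not analysed. Of 15 tested members of the pachytene and later spermatocyte list, 9 fell, with a median log2 fold change of -1.48 that turned to 0.04 under RLE scaling of the listed transcripts. The germ-cell glycolytic enzyme Pgk2 (-2.97) and the sperm lactate dehydrogenase Ldhc (-1.33) fell. The heat shock protein Hspa2 (-1.05 ± 0.28, adjusted p = 0.0929) and the Piwi protein Piwil1 (-1.48 ± 0.49, adjusted p = 0.161) did not pass. Of 7 tested members of the meiotic division list, 4 fell (median -1.60), among them the phosphatase Cdc25c (-2.85 ± 0.53, adjusted p = 0.0364) and the kinase Plk1 (-1.64 ± 0.25, adjusted p = 0.025), while the cyclin Ccnb1 was at -1.14 ± 0.31 (adjusted p = 0.0971). Under TMM, RLE and upper quartile scaling of the listed transcripts, edgeR called 1, 1 and 2 spermatocyte members lower (Pgk2, joined by Spag6 under upper quartile) and 0, 0 and 0 division members, with 1, 0 and 2 division members at an unadjusted p under 0.05 and division medians of -0.12, -0.05 and -0.52. These scalings take the bulk of a table of called transcripts as unchanged, which by construction moves the centre. Library totals do not, and with them edgeR called 5 spermatocyte and 2 division members lower, with medians of -0.96 and -1.08. DESeq2 called all 15 and 7 lower, and glmTreat against a fold of 2 called 2 and 0 lower, with 8 and 4 at an unadjusted p under 0.05. With p-values adjusted over the list alone, 15 of 15 spermatocyte and 7 of 7 division members fell. Neither list passed camera, with adjusted p = 0.0745 for spermatocytes and 0.266 for divisions, and adjusted p = 0.585 and 0.574 with an estimated correlation. By fry, which does not compare a list with other genes, both were lower (adjusted p = 0.0228 and 0.0131), on members the authors had picked for change. The spermatocyte list did pass camera with equal Sertoli counts (adjusted p = 0.0183), by limma-voom (0.0168) and with a replicate block (0.0208). Its median stayed between -1.73 and -1.30 without any one library.

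Listed genes of meiotic prophase did not move together. Of 20 synaptonemal complex, 30 recombination and 20 piRNA members, 15, 18 and 13 were not among the listed transcripts and so were not analysed. In the elongating and round spermatid lists that held for 1 of 34 and 0 of 32 members. In the synaptonemal complex list, Syce2 fell from 1410 ± 184 to 410.7 ± 123 (-1.78 ± 0.32, adjusted p = 0.0333), the only one of 5 tested members to pass, and Syce1 was at -1.10 ± 0.24 (adjusted p = 0.0509). The list's median of -1.21 turned to 0.26 under TMM and 0.35 under RLE scaling. In the recombination list, 2 of 8 tested members fell, Psmc3ip (-1.28 ± 0.27, adjusted p = 0.0484) and 4930432K21Rik (-1.29 ± 0.25, adjusted p = 0.0387). Msh4 (-1.52 ± 0.44) and Hsf2bp (-1.25 ± 0.29) did not pass. That list's median was -1.19 and its camera direction was up (adjusted p = 0.697). Its mean of 0.45 rests on the fitted value of 1 member at 0 in a genotype, and the sign of the mean turns with that member's bound. The median turned to 0.29 under TMM and 0.36 under RLE. In the piRNA list, Rnf17, Gtsf1 and Mael fell, the listed Tdrkh transcript rose from 0 to 122.7 ± 70.2 (at least 68.4-fold higher), and Tdrd6 was at -1.05 ± 0.25 (adjusted p = 0.067). The piRNA median of -1.20 turned to 0.28 under TMM and 0.36 under RLE, and camera gave adjusted p = 0.975. The list's mean of 0.20 rests on the fitted log2 fold change of 9.99 for Tdrkh, bounded at 6.1, and its sign turns with that bound. Under TMM edgeR called 1 synaptonemal complex, 3 recombination and 2 piRNA members higher and 0 of each list lower, with 1, 3 and 4 at an unadjusted p under 0.05, and with equal Sertoli counts it called 0, 0 and 1 higher and 4, 5 and 5 lower, with 4, 6 and 6 at an unadjusted p under 0.05. Under library totals the synaptonemal complex, recombination and piRNA medians stayed negative, at -0.68, -0.66 and -0.67. There edgeR called 0, 2 and 2 members higher and 0, 0 and 1 lower, with 3, 5 and 6 at an unadjusted p under 0.05. Adjusted over the list alone, 1 synaptonemal complex member rose and 4 fell, 3 recombination members rose and 5 fell, and 2 piRNA members rose and 5 fell.

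Of 18 meiotic entry, 16 differentiating and 22 undifferentiated spermatogonia members, 12, 7 and 15 were not among the listed transcripts. Around meiotic entry, the cohesin Rec8 fell from 1380 ± 324 to 278.3 ± 46 (-2.31 ± 0.31, adjusted p = 0.0207). The listed transcripts of Ccnb3 and Ugt8a rose from 0 in both WT libraries to 114.6 ± 53.1 and 30.07 ± 18.5, at least 63.8-fold and 16.8-fold higher. Stra8, which is induced by retinoic acid at the start of meiosis, was at 136.6 ± 34.9 in the WT and 304.0 ± 5.81 in the cKO and did not pass (1.15 ± 0.34, adjusted p = 0.12). The list's median of 1.09 turned to -0.21 with equal Sertoli counts (camera adjusted p = 0.155). Of 9 tested members of the differentiating spermatogonia list, the cyclin Ccnd2 rose (1.39 ± 0.27, adjusted p = 0.0412) and Dmrtb1 and Tex13a fell, while the receptor Kit (1.85 ± 0.49, adjusted p = 0.0883) and Sohlh1 (1.64 ± 0.44, adjusted p = 0.091) did not pass. Its median of 1.09 turned to -0.20 with equal Sertoli counts (camera adjusted p = 0.143). Of 6 tested members of the undifferentiated list, a transcript of Lhx1 fell from 21.01 ± 2.65 to 0.56 ± 0.792 normalized counts (log2 fold change -5.34). The stem cell factor Zbtb16 (1.47 ± 0.38, adjusted p = 0.0823) and the receptor Ret (2.76 ± 0.62, adjusted p = 0.0573) did not pass. This list's median was 1.31, or 0.02 with equal Sertoli counts, and 1.11 and 1.58 without WT replicate 1 or 2. Its camera adjusted p was 0.0901 (adjusted p = 0.574 with an estimated correlation). With a filter of 1 CPM in 2 samples it passed camera (adjusted p = 0.0207), but Lhx1, its only tested member that fell, had then dropped out. By fry, which does not compare a list with other genes, the undifferentiated list was higher (adjusted p = 0.0394). The entry and differentiating lists did not pass fry (adjusted p = 0.086 and 0.231). The authors had picked all these members for change. Under TMM edgeR called 4 entry, 6 differentiating and 5 undifferentiated members higher and 0 of each list lower, with 5, 7 and 6 at an unadjusted p under 0.05. With equal Sertoli counts it called 1, 0 and 0 higher and 2, 3 and 1 lower, with 4, 3 and 1 at an unadjusted p under 0.05, and DESeq2 called 2, 4 and 3 higher and 2, 2 and 0 lower. Adjusted over the list alone, 4, 6 and 5 members of the entry, differentiating and undifferentiated lists rose and 2, 3 and 1 fell.

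Part of the Sertoli, Leydig and leukocyte transcripts rose in the cKO, while the myoid and endothelial lists went both ways. The Sertoli transcription factor Sox9 rose from 296.7 ± 4.46 to 737.4 ± 62 (1.31 ± 0.26, adjusted p = 0.0423), the inhibin subunit Inha rose by 1.88 and clusterin, Clu, by 1.25 on the log2 scale, while Wt1 was at 1.33 ± 0.41 (adjusted p = 0.131). In Leydig cells, the steroidogenic enzymes Cyp17a1 (3737 ± 360 to 14570 ± 4070, 1.96 ± 0.29, adjusted p = 0.0242), Cyp11a1 (1.71 ± 0.30, adjusted p = 0.0332) and Hsd3b6 (3.15 ± 0.37, adjusted p = 0.0181) rose. The listed transcript of another Leydig enzyme, Hsd17b3, went the other way, with 162.4 and 3.84 normalized counts in the WT libraries and 0 in both cKO libraries, and was not tested because it lay below the count filter. Among leukocyte transcripts, the macrophage receptor Csf1r rose from 249.3 ± 31.2 to 845.8 ± 122 (1.76 ± 0.28, adjusted p = 0.0275) and the lysozyme Lyz2 by 2.02, while Cd68 was at 1.81 ± 0.54 (adjusted p = 0.121). The members that rose, adjusted over the list alone, were 22 of 22 Sertoli, 13 of 13 Leydig and 10 of 10 leukocyte transcripts. Of 30 Sertoli, 20 Leydig and 20 leukocyte members, 8, 6 and 10 were not among the listed transcripts. By camera the 3 lists were higher, with adjusted p = 2.53e-06, 3.45e-05 and 0.000203, and these calls were lost with adjusted p = 0.544, 0.429 and 0.429 with an estimated correlation. With equal Sertoli counts the Leydig and leukocyte medians were 0.25 and 0.59 and only Hsd3b6 passed, and glmTreat against a fold of 2 called 0 Sertoli, 1 Leydig and 0 leukocyte members, with 11, 8 and 9 at an unadjusted p under 0.05.

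In the retinoic acid list, the retinal dehydrogenase Aldh1a1 rose from 4499 ± 992 to 14510 ± 724 (1.69 ± 0.26, adjusted p = 0.0258) and the listed transcript of the receptor Rara rose from 0 to 152.4 ± 74.1, at least 84.9-fold higher. A transcript of the partner receptor Rxra fell from 411.0 ± 102 to 31.6 ± 8.49 (-3.69 ± 0.42, adjusted p = 0.0175), and the retinoic acid hydroxylase Cyp26b1 was at 1.03 ± 0.32 (adjusted p = 0.136). The list was higher by camera (median 1.43, adjusted p = 0.0193, and adjusted p = 0.574 with an estimated correlation). Under TMM 7 members rose, and with equal Sertoli counts the median was 0.13 and 1 member, Rara, rose. In the cholesterol synthesis list, 8 of 12 tested members rose, among them the reductase Dhcr7 (1.96 ± 0.30, adjusted p = 0.026) and Msmo1 (2.45 ± 0.36, adjusted p = 0.0241). The squalene synthase Fdft1 fell by 1.47 (adjusted p = 0.0341), turning to 0.01 under TMM and 0.08 under RLE. That list was also higher by camera (median 1.74, adjusted p = 0.00125, and adjusted p = 0.429 with an estimated correlation). Under TMM 10 members rose, and with equal Sertoli counts the median was 0.44 and edgeR called 0 members higher and 2 lower, with 4 at an unadjusted p under 0.05. glmTreat against a fold of 2 called 0 of the 12 cholesterol members, with 9 at an unadjusted p under 0.05. Sertoli and Leydig transcripts, with medians of 1.35 and 1.56, were higher by about as much as these lists. Adjusted over the list alone, 7 retinoic acid members rose and 1 fell, and 10 cholesterol members rose and 2 fell. Of 21 retinoic acid and 18 cholesterol members, 13 and 6 were not among the listed transcripts.

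Some listed subunits of PP2A itself fell, and by edgeR on all 4 libraries under the authors' size factors 0 passed as higher. The scaffold Ppp2r1b fell from 1306 ± 89.7 to 346.7 ± 93 (-1.91 ± 0.30, adjusted p = 0.0263), as did the regulatory subunits Ppp2r2b (-5.28), Ppp2r2d (-1.37) and Ppp2r5c (-1.15). The scaffold Ppp2r1a was at 1.06 ± 0.25 (adjusted p = 0.0619), turning to -0.24 with equal Sertoli counts. Of 23 PP2A members, 13 were not among the listed transcripts. Of 10 tested members 4 fell, and 4 rose and 6 fell adjusted over the list alone. glmTreat against a fold of 2 called 0 of the 10, with 4 at an unadjusted p under 0.05. The calls turned with the scaling and with the test. Under TMM edgeR called 4 members higher (Ppp2r1a, Ppp2r3a, Strn3 and Igbp1) and 0 lower, with 5 at an unadjusted p under 0.05, under RLE and upper quartile 4 higher and 1 lower, under library totals 2 each way, and with equal Sertoli counts 0 higher and 6 lower. DESeq2, which kept the authors' size factors, called 2 higher and 5 lower. The median of -1.18 was -0.65 under library totals and turned to 0.30 under TMM and 0.38 under RLE, and camera gave the opposite direction, up, with adjusted p = 0.872.

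The myoid, endothelial, p53 and DNA replication lists did not pass camera, and lists with fewer than 3 tested members were not tested with it. In the peritubular myoid list, the smooth muscle actin Actg2 fell from 3420 ± 577 to 174.6 ± 20.5 (-4.29 ± 0.29, adjusted p = 0.0154) and Synpo2 fell to 0, while the kinase Mylk rose (1.52 ± 0.31, adjusted p = 0.0455). Actg2 fell by about as much as the elongating spermatid list (median -3.96), and which cells gave its reads was not tested. The myoid median of 1.14 and the camera direction, up, differed in sign from the mean of the 5 tested members, -1.60. That median turned to -0.17 with equal Sertoli counts. In the endothelial list, Pecam1 rose from 1 count in the WT to 71 in the cKO, a ratio of 47.7 with an exact 95% counting interval of 8.29 to 1910, Robo4 rose from 0 (at least 10.1-fold higher), and a transcript of Egfl7 fell to 0 (at least 23.2-fold lower). Its median was 5.32, or 3.33 with transcripts at their bounds, and -0.41 without a low-count filter. The rises of Pecam1 and Robo4 did not pass without that filter or with equal Sertoli counts, the fall of Egfl7 did not pass under TMM and RLE, and glmTreat against a fold of 2 called 0 of these 3 transcripts, all at an unadjusted p under 0.05. In the p53 and apoptosis list, the listed Zmat3 transcript rose from 0 to 290.0 ± 24.6 (at least 162-fold higher) and a Bcl2l11 transcript fell from 90 counts to 3, a ratio of 44.7 with an interval of 14.8 to 221, while Ccng1 (1.25 ± 0.30) and Trp53inp1 (1.20 ± 0.46) did not pass. That list's median of 1.23 turned to -0.06 with equal Sertoli counts. Under TMM 3 myoid and 4 p53 members rose, and with equal Sertoli counts 0 and 1 rose and 2 of each list fell, with 2 and 3 at an unadjusted p under 0.05. The camera adjusted p was 0.872 for myoid, 0.32 for endothelial and 0.121 for p53 genes. Adjusted over the list alone, 3 myoid, 2 endothelial and 4 p53 members rose and 2, 1 and 2 fell. Of 15 myoid, 14 endothelial and 21 p53 members, 10, 10 and 15 were not among the listed transcripts.

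The only listed member of the red blood cell list, Hemgn, which spermatids also express, fell from 2422 ± 333 to 118.7 ± 81 (-4.35 ± 0.57, adjusted p = 0.02). In the epididymis list, Wfdc10 was at 1.06 ± 0.34 (adjusted p = 0.145), turning to -0.24 with equal Sertoli counts. Among DNA replication genes Cdt1 (1.48 ± 0.44) and Pola1 (1.10 ± 0.32) did not pass, nor did the Wnt targets Lef1 (-1.34 ± 0.41) and Bambi (-1.11 ± 0.31). Of 24 replication members, 21 were not among the listed transcripts. Of the epididymis, replication and Wnt lists, edgeR called 0 of 1, 0 of 3 and 0 of 2 tested members, and DESeq2 called 0, 1 and 0. All had an unadjusted p under 0.05 by edgeR, as did 10713 of all 10716 tested transcripts, since the table holds only called ones. Under TMM, RLE, upper quartile and library totals edgeR called 2 replication members, Cdt1 and Pola1, higher, and with equal Sertoli counts it called 1, Pole, lower. The DNA replication median of 1.10 turned to -0.19 with equal Sertoli counts (camera adjusted p = 0.435), and both Wnt targets turned positive under TMM and RLE. Adjusted over the list alone, Hemgn and both Wnt targets fell, Wfdc10 rose, and 2 replication members rose and 1 fell.

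Over all listed transcripts, 4436 fell and 1119 rose among 10716 tested, and 5161 did not pass. The called transcripts fell by a median of 8.95-fold and rose by a median of 6.89-fold with transcripts at 0 in a genotype at their bounds (8.98 and 8.83 with fitted values). By gene, 2836 lead transcripts fell and 795 rose. Of 2318 genes with 2 or more listed transcripts, 410 had listed transcripts in both directions. Of 4040 genes with a called transcript, 145 had calls both ways, so a lead transcript need not stand for its gene. Scaling decided the balance of directions. The TMM scaling planned at first, which takes most listed transcripts as unchanged, gave 3446 higher and 1223 lower, RLE 3479 and 1331, upper quartile 3434 and 2073, library totals 2793 and 3194, and equal Sertoli counts 319 and 7177. Library totals shift the cKO over WT ratio by 0.53 on the log2 scale relative to the authors' size factors, TMM shifts the median of the tested transcripts by 1.48, RLE by 1.55, upper quartile by 1.09 and equal Sertoli counts by -1.30. Of the lists tested with camera, all but the spermatid lists had call counts under RLE and upper quartile within 1 of those under TMM. Leaving out WT replicate 1 or 2 left 0 calls by edgeR in any list, with 8351 and 8343 transcripts at an unadjusted p under 0.05 and lowest adjusted p of 0.135 and 0.144, since the spread then comes from the cKO pair alone. Leaving out cKO replicate 1 or 2 gave 7484 and 8461 calls.

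The transcripts with the largest fitted changes were single isoforms at 0 in one genotype. The listed transcripts of Mfap3, Mark2, Phactr4, Abhd14a and Prrc2c were at 0 in both WT libraries and rose to between 454.5 and 652.8 in the cKO, at least 364, 338, 315, 278 and 253-fold higher. Those of Zan, a sperm protein that binds the zona pellucida, and of Coro2a, Usp2, Aldoart1 and the sperm channel subunit Catsperg1 fell to 0 after rounding in both cKO libraries from WT means of 1920 to 3377, at least 2800, 2050, 1970, 1740 and 1590-fold lower. Each of these 10 genes has 2 or more annotated transcripts, and another Zan isoform went from 0 to 321.4 ± 182. These values describe the isoform and not the gene.

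X-linked genes were more often higher in the cKO than autosomal genes. Of 437 listed X-linked genes, 227 were higher (51.9%, 95% Wilson interval 47.3% to 56.6%), against 2480 of 6911 autosomal genes (35.9%, 34.8% to 37.0%) by the direction in the authors' deposited table. The share differed by 16.1 percentage points (two-sided Fisher's exact test p = 4.23e-11), and by 22.3 points without predicted genes. The median log2 fold change was 1.06 for X-linked and -1.43 for autosomal genes, a difference of 2.49. The X-linked set was higher by camera (p = 0.00408, and p = 0.0328 with an estimated correlation), but its mean was -0.35 and fry, which does not compare it with other genes, gave the direction down (p = 0.00518). Among calls of the refit, 59 X-linked genes rose and 133 fell, against 734 and 2656 autosomal ones (Fisher's exact test p = 0.00419). Because each gene had to reach a 2-fold change to be listed, the medians fall on either side of a gap and overstate the shift of the whole class.

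**Figure D3:**
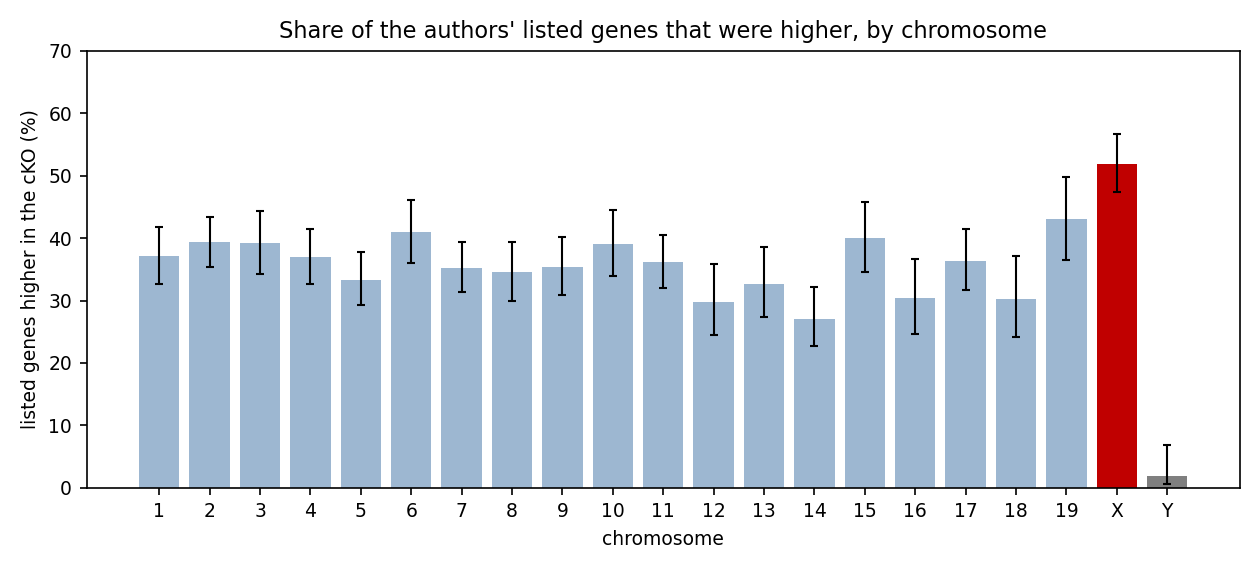
Percent of the authors' listed genes on each chromosome whose lead transcript was higher in the cKO, with 95% Wilson intervals, the X chromosome in red and the Y chromosome in grey. The X chromosome stood at 51.9%, the autosomes between 27.1% and 43.1%, and the Y chromosome at 1.94%.

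On the Y chromosome 101 of 103 listed genes were lower. The 2 higher ones were Ddx3y and Uty, both named after their values were seen and both found in single copy. Another listed Uty transcript was lower in the cKO. The lower genes included Sly, Ssty2 and Srsy, members of multi-copy families expressed in spermatids, and many predicted genes. Reads of such families are shared between near-identical copies, so single members are uncertain.

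The authors' deposited table lists 3736 transcripts as higher and 7568 as lower in the cKO. All 10716 transcripts tested in the refit had the direction given there, and 5555 of them passed at an adjusted p under 0.05. The refit used the authors' counts and size factors on transcripts picked by fold, so the shared direction was fixed in advance.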

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

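The adjustment over the listed transcripts alone was chosen after seeing the data. The split of directions followed the scaling. Under TMM of the listed transcripts 3446 transcripts were higher and 1223 lower, under RLE 3479 and 1331, under upper quartile 3434 and 2073, under library totals 2793 were higher, and with equal Sertoli counts 319 and 7177. TMM, RLE and upper quartile take the bulk of a table of called transcripts as unchanged, which by construction moves the centre. DESeq2 called 2003 higher. glmTreat against a fold of 2 called 2355 in all (281 higher, 2074 lower), all with the direction of the authors' table (2355), which the shared counts and size factors fixed in advance. It called 0 members of the PP2A, differentiating spermatogonia, synaptonemal complex, recombination, division, Sertoli, leukocyte, endothelial, DNA replication and cholesterol lists. Adjusted over the listed transcripts alone, 10713 passed (3489 higher, 7224 lower), since fewer tests were counted. Leaving out each library, the calls ranged from 0 to 8461, higher calls from 0 to 2291, lower calls from 0 to 6170 and calls sharing the authors' direction from 0 to 8461. The values of 0 came from leaving out WT replicate 1 or WT replicate 2, with the single WT library assumed to vary like the cKO pair. The number of lists that passed was 7, and 7 to 9 in the alternatives except 0 with an estimated correlation (lowest adjusted p = 0.429) and 13 by fry. The X-linked minus autosomal median stayed between 2.26 and 2.54 and on the same side of the threshold in each alternative that gave it. Another scaling moves both classes almost alike, so the scaling alternatives could not test this difference.

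Under TMM these log2 values turned positive, with the cause not tested beyond that shift: Syce1 0.38, Hsf2bp 0.23, Hspa2 0.44, Ccnb1 0.34, Tdrd6 0.44, Lef1 0.14, Bambi 0.37, Fdft1 0.01, and the medians of the PP2A (0.30), synaptonemal complex (0.26), recombination (0.29) and piRNA (0.28) lists. Under RLE they were Syce1 0.44, Msh4 0.03, Hsf2bp 0.31, Piwil1 0.04, Hspa2 0.50, Ccnb1 0.43, Tdrd6 0.50, Lef1 0.22, Bambi 0.43, Fdft1 0.08, and the PP2A (0.38), synaptonemal complex (0.35), recombination (0.36), spermatocyte (0.04) and piRNA (0.36) medians. Under upper quartile Hspa2 and Tdrd6 were each at 0.04. With equal Sertoli counts these turned negative: Ppp2r1a -0.24, Stra8 -0.14, Wfdc10 -0.24, Ccng1 -0.05, Trp53inp1 -0.08, Cyp26b1 -0.26, Pola1 -0.19, and the medians of the differentiating spermatogonia (-0.20), meiotic entry (-0.21), myoid (-0.17), p53 (-0.06) and DNA replication (-0.19) lists. Without a low-count filter the endothelial median was -0.41, since Ets1 then entered a list of 3.

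The replicate numbers were not taken as pairs, since 2 pairs are too few and the labels name no shared litter or day. Replicate deviations of the 2 genotypes correlated at 0.11 (Pearson) and 0.23 (Spearman) across 10349 transcripts, which are not independent. With the replicate block 4609 transcripts were called, 697 higher and 3912 lower, among them 13 of 15 spermatocyte members, whose list then passed camera (adjusted p = 0.0208), and 0 of 3 endothelial members, with 3 at an unadjusted p under 0.05. All 32 round and 33 elongating spermatid members were called lower with the block. Lhx1 and Ccnd2 did not pass with it, which left 0 undifferentiated calls and 0 higher and 2 lower differentiating calls. In the entry list it called 1 member higher and 2 lower. No setting gave a value for Ppp2ca, and alternatives for normalized values were not run because counts were used. In the simulated counts, changes of 2-fold were mostly not called. With 50 transcripts changed at each fold there, against 5555 calls in the data, the adjustment was stricter, so that share does not carry over to the data.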

Other observations

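The gene ontology, biotype, size factor and permutation tests here were all chosen after the results were seen. Among the 7453 listed genes, 36.4% were higher in the cKO, and 149 of 527 gene ontology terms with at least 15 listed genes departed from that share (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted). Terms that leaned toward higher values were led by membranes and secretion, with 143 of 245 endoplasmic reticulum genes (adjusted p = 3.92e-10), 113 of 188 extracellular space genes (4.88e-09) and 72 of 110 cell surface genes (6.78e-08). Lysosomal membrane genes (25 of 33, adjusted p = 0.000111), the response to lipopolysaccharide (30 of 42, 0.000121) and the mitochondrial inner membrane (57 of 91, 1.65e-05) leaned the same way. Terms that leaned toward lower values included the centrosome (85 of 105 lower, adjusted p = 0.00166), the acrosomal vesicle (39 of 45, 0.00753), the motile cilium (20 of 21, 0.00971), the binding of sperm to the zona pellucida (17 of 17, 0.00538) and the nuclear pore (15 of 16, 0.0375). Genes for the detection of odorants, of which some are expressed in male germ cells, were also lower, in 25 of 26 (0.00177), and so were genes of olfactory receptor activity, in 28 of 33 (0.041). The related term for the perception of smell was not, with 6 of 15 lower (0.136).

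Of 463 listed pseudogenes, 28 were higher (6.05%, 95% Wilson interval 4.22% to 8.6%), against 38.5% of 6957 protein-coding genes, and pseudogene reads can belong to their parent genes. Within 5 classes of abundance, X-linked genes were higher more often than autosomal ones by 11.1 percentage points (permutation p = 0.0001, the smallest that 10000 permutations can give). The mitochondrial cytochrome oxidase transcript mt-Co3, singled out after its values were seen, stood at 4.72 and 0.351 normalized counts in the WT libraries and at 1376 and 867 in the cKO libraries (adjusted p = 0.0154). It was the only listed mitochondrial transcript, and its level in the WT lies far below what a mitochondrial messenger usually reaches.

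The germ cell lists were lower by stage. The hypothesis that later stages fell further was tested over genes by permuting list membership (100000 permutations, 2-sided). The median of the round spermatid list lay below that of the spermatocyte list (difference -1.57 on the log2 scale, permutation p = 0.0015), and that of the elongating list lay below that of the round list (-0.86, permutation p = 0.00062). Without cKO replicate 2 the elongating and round medians were -4.75 and -3.41, and without cKO replicate 1 they were -3.45 and -2.82, so the size of the second difference depended on the library left out. Genes of a list share cells and are not independent, so these p-values are likely too small. Another scaling moves each list almost alike and so changes these differences little.

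Elongating spermatid transcripts were higher in cKO replicate 2 than in cKO replicate 1, for which depth or scaling of that library is argued against, since the median log2 ratio of the 2 libraries lay 1.49 higher in the elongating list than in the Sertoli list (permutation p = 2e-05). Wild-type RNA mixed into the library stays open and may account for it, because the excess came to 5.07% of the WT mean in the elongating list and 5.11% in the round list, a difference of -0.0397 percentage points (95% bootstrap interval -1.82 to 1.91). In 166 genes with 1 annotated transcript, a WT mean of at least 1000 and a fall of at least 4-fold in the authors' table, 1 (Gm10297) lay under 2.5% of its WT mean in cKO replicate 2, against 29 in cKO replicate 1. Against it, 31 of 769 such transcripts from genes with 2 or more annotated transcripts lay under that bound in cKO replicate 2, and 14 of them, Zan, Coro2a, Usp2, Aldoart1 and Catsperg1 included, under 0.5%, which such a share forbids unless the reads of these genes were divided differently among isoforms. A small share of tubules with complete spermatogenesis would give the same values, and the labels name no biological difference between these replicates, so none was tested.

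The tested Sertoli, Leydig and leukocyte lead transcripts had higher values in the cKO. Another scaling moves all ratios alike. Library totals moved them up by 0.53 on the log2 scale, with medians of 1.88, 2.08 and 2.41 and 20, 12 and 8 calls. Against library totals the authors' size factors thus made the rise smaller, but an upward shift could not turn transcripts listed as higher. Equal Sertoli counts moved the ratios down, by construction, with Leydig and leukocyte medians of 0.25 and 0.59 and 1 of 23 members passing. Against such a scaling the size factors stay open as the source. A lower share of germ cell RNA alone would raise the 3 lists alike, and their medians of 1.35, 1.56 and 1.89 differed by up to 0.54 (permutation p = 0.0061). That test is void, because no more than 10 of 20 leukocyte genes are in the table and low-count transcripts had to change more to enter it, and with no value left that decides, the size factors, a lower share of germ cell RNA and a change within somatic cells cannot be told apart for these lists. The genotype itself stays an open biological explanation.

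Of transcripts with a mean over 50 normalized counts, 94 were at 0 in both WT libraries and 128 in both cKO libraries, and 2 of these, from genes outside GENCODE vM21, were left out of the test. Reads of a gene divided differently among its annotated transcripts are a candidate explanation. Of 7125 such transcripts from genes with 2 or more annotated transcripts, 217 were at 0 in a genotype (3.05%), against 3 of 896 (0.335%) from genes with 1, namely Gm10297, Fam205a2 and Gm2541. Within 5 classes of abundance the difference was 2.7 percentage points (permutation p = 0.0001, the smallest possible), and in 79 of the 217 another listed transcript of the gene went the other way. A true isoform switch between germ cell and somatic transcripts would give the same values, and that biological explanation was not tested.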
